A study of Mus musculus with 32 samples.

How the data were processed

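RNA was sequenced from mouse photoreceptors, the light-sensing rods and cones of the retina, cut out of snap-frozen eyes by laser capture microdissection. Per the labels' protocols, the animals were 6-week-old males on a C57BL/6/J x 129 SvEvBrd background, RNA was isolated with the Qiagen RNeasy Micro kit and libraries were made with the KAPA mRNA HyperPrep kit. The 2 genotypes were wild type (WT) and Per1-/-Per2Brdm1 (KO), and the 4 times were circadian times (CT) 19, 22, 1 and 10, which count hours of the internal day from subjective dawn. Each of the 8 groups held 4 libraries, 32 in all, and every library was assigned to its group by its label.

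The values used are raw read counts per Ensembl gene for all 32 libraries, as deposited by the authors in 1 table of 54232 genes. Per the submitters' processing notes, the tools were Trimmomatic 0.32, HISAT2 2.1.0, Cufflinks and HTSeq 0.11, with genome build GRCm38.p6. The order of these steps, the role of Cufflinks, the annotation release, the strand setting and the treatment of reads matching several places are not given in the sources used here. Without the strand setting, reads from a gene and from a gene overlapping it on the other strand cannot be told apart, and reads shared by near-identical genes may be split or dropped. Of the 61 genes picked by the naming rule for their size of change, their p-value or their place in the core clock list, 10 share annotated exons with a tested gene on the opposite strand: Bhlhe41, Csnk1d, Dbp, Dnah9, Gdpd3, Kif4, Nr1d1, Rgs20, Tef and Tpbgl. List members named below share exons in the same way, among them Pde6h, Gnb5, Pfkm, Hk1, Glul, Grm6, Junb, Dusp1, Manf, Gas6, Rac1 and Cabp4. The values of all these genes are less certain for that reason. Gene names and positions came from the GENCODE mouse annotation of GRCm38, which named 99.9% of the gene identifiers. A total of 19506 genes had a count of 0 in all libraries.

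Library totals ranged from 23833604 to 34582742 counts, so a transcript at 1 CPM (counts relative to library size, before TMM scaling) rested on at least 23.8 counts in every library. The tested genes held at least 99.9% of the counts of each library. No 2 libraries were identical, and all pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 11.4 to 100.1). The labels give animal numbers, and the p-values treat the libraries as separate animals as far as these numbers say. In the WT group at CT1, the library called replicate 5 carries 2 animal numbers in its title, and it was used as 1 library.

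Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 8 groups (minimum count 10, minimum total 15), which left 17871 genes, and libraries were scaled by TMM. All 32 libraries entered 1 negative binomial fit with a mean for each group, giving 24 residual degrees of freedom and a biological coefficient of variation of 0.199, and contrasts were tested with edgeR's robust quasi-likelihood test. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, and a gene is called when its adjusted p is under 0.05. An adjusted p given without the name of another tool is from this test. The contrasts were KO against WT over the mean of the 4 times and at each time, any difference among the 4 times within WT and within KO (F tests with 3 contrasts, which assume no shape of rhythm), the genotype by time interaction (also an F test with 3 contrasts), and CT1 against the mean of the other 3 times within each genotype. For an F test, the size given is the range of the fitted group means over the times, in log2 units, or for the interaction the range of the 4 KO-WT differences. CPM values are TMM-scaled and given as mean ± SD over libraries.

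A total of 32 gene lists, for pathways of photoreceptors and for markers of other cell types of the eye, were fixed before the data were examined, as were the groups, contrasts, alternative settings and the rule for naming genes. Lists with at least 5 tested members were tested against all other tested genes with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of each contrast, and again with a correlation estimated per list. For each list the text gives how many members were called over all genes and how many when adjusted over the list alone. The rule named Per1 and Per2 in every group, then every member of the core clock list. For the mean contrast it took the 10 highest and 10 lowest fold changes among called genes with the same sign at all 4 times, and at single times the 3 highest and 3 lowest. For the F tests it took the 12 smallest p-values, and within lists up to 4 members with the smallest p. Genes had to have an average log2 CPM of at least 1 and a symbol that was neither provisional nor that of a pseudogene. Some genes that the rule picked are not reported here.

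The procedure was tested on simulated counts with known changes. In each comparison 67 genes were changed 1.5-fold and 67 were changed 2-fold, drawn from genes above a low expression limit. Each gene was simulated separately, so variation shared by many genes, such as that of lens or inner retinal markers, was left out. The rates may therefore be too high for the real libraries. For the mean contrast (17609 simulated genes tested) it recovered 88.1% of genes changed 1.5-fold and 92.5% of those changed 2-fold, for CT22 alone (17582 genes) 50.7% and 82.1%, for time in WT (17648 genes) 47.8% and 88.1%, for the interaction (17637 genes) 25.4% and 70.1%, and for CT1 against the other times in WT (17618 genes) 58.2% and 85.1%.

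Other settings tried were DESeq2 1.42.0, limma voom with library quality weights, other size factors, other count filters, an adjusted p under 0.1, an absolute log2 fold change of at least 0.58, a cosine curve with a 24 h period, the replicate number or the set of 8 libraries by serial number as a term, marker levels of inner retinal cells or of the pigment epithelium as a covariate, only the libraries of the groups compared, leaving out the genes around Per1 and Per2 (200 annotated neighbours on each side), and leaving out each library in turn. Another 3 were added after the data were seen: the level of lens markers as a covariate, the inner retina and lens levels together, and a fit without the CT10 libraries. For other splits of the libraries, group labels were shuffled within times (genotype, interaction) or within a genotype (time) until there were 80 splits, the real one included, a number set by the run time. At single times all 35 splits of 4 against 4 were counted.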

Results

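Gene expression was measured in microdissected mouse photoreceptors of 2 genotypes, WT and Per1-/-Per2Brdm1 (KO), at CT19, CT22, CT1 and CT10, with 4 libraries in each of the 8 groups. Per1 and Per2 are transcriptional repressors of the circadian clock, and the Brdm1 allele of Per2 is known as a deletion within its PAS domain. The study asked how these genes take part in the daily rhythm of outer segment phagocytosis, in which the pigment epithelium engulfs the shed tips of photoreceptors, and eyes were taken before, during and after the peak of that rhythm. Library totals ranged from 23833604 to 34582742 counts.

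The targeted genes were read in every group. Per1 (ENSMUSG00000020893, GRCm38 chromosome 11, 69095217 to 69109960, plus strand) stood in WT at 131 ± 9.62 CPM at CT19, 131 ± 14.6 at CT22, 109 ± 22.7 at CT1 and 102 ± 3.93 at CT10 (SD, n = 4 each). In KO it stood at 221 ± 47.5, 227 ± 66.6, 196 ± 9.80 and 188 ± 13.1 CPM at the same times. Per2 (ENSMUSG00000055866, chromosome 1, 91415982 to 91459324, minus strand) stood in WT at 36.2 ± 2.05, 35.1 ± 4.43, 30.6 ± 9.22 and 21.1 ± 6.79 CPM, and in KO at 187 ± 18, 208 ± 43.2, 196 ± 18 and 202 ± 12.1 CPM. Both genes were thus higher in KO at every time, by 0.82 (SE 0.07) for Per1 and 2.72 (SE 0.09) for Per2 on the log2 scale over the mean of the 4 times (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.17e-09 and 2.58e-19). Counts summed over a whole gene include exons outside the deleted part, so they check nothing about the deletion itself, but the 16 KO libraries (Per2 168 to 267 CPM) and the 16 WT libraries (15.2 to 44.3 CPM) did not overlap.

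**Figure D1:**
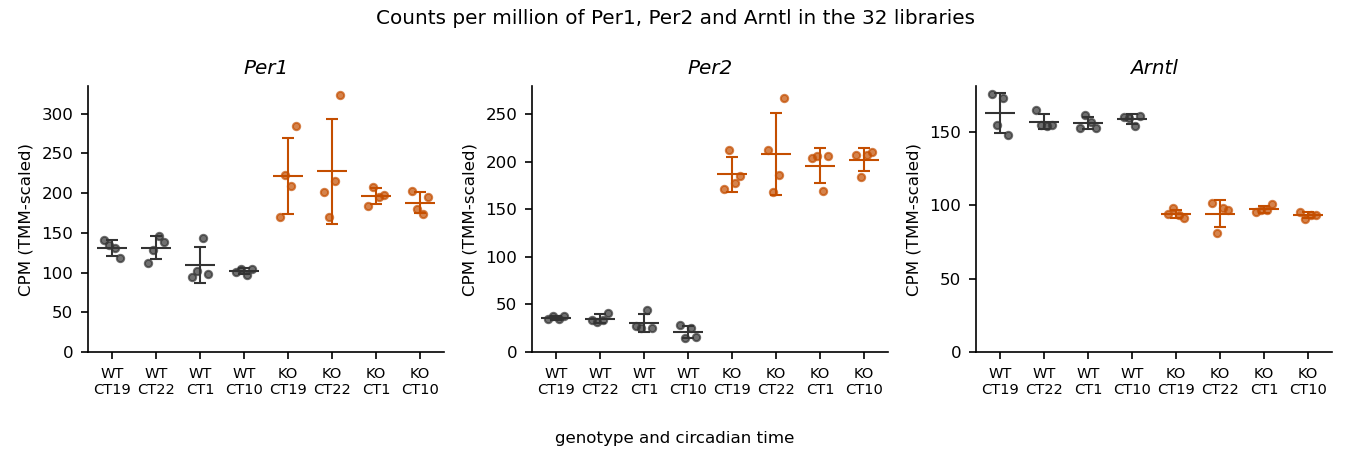
Normalised expression (CPM, TMM-scaled) of Per1, Per2 and Arntl in the 32 libraries by genotype and circadian time, with points for libraries and bars for the mean and SD of 4. Per2 lay between 168 and 267 CPM in the KO libraries and between 15.2 and 44.3 CPM in the WT libraries.

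The first comparison asked which transcripts differed between KO and WT over the mean of the 4 times. Col4a3, a chain of basement membrane collagen, was 8.01-fold higher in KO (223 ± 41.0 CPM against 28.7 ± 12.1 in WT, SD, n = 16), and Akap5, an anchoring protein of protein kinase A, was 6.18-fold higher (12.1 ± 2.77 against 2.11 ± 1.09 CPM). Gzmm, a granzyme protease, rose from 43.7 ± 9.92 to 169.7 ± 22.5 CPM and Rasl10b, a small GTPase of the Ras family, from 28.1 ± 3.99 to 100.1 ± 11.7 CPM. In the other direction Fabp7, a brain-type fatty acid binding protein, fell from 4.50 ± 1.80 to 0.215 ± 0.133 CPM, and Fscn2, a retinal actin-bundling protein, fell from 142 ± 22.3 to 54.6 ± 8.98 CPM. Hcls1, a cortactin-related protein of blood cells, fell from 74.5 ± 13.6 to 16.1 ± 3.61 CPM.

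In total 2909 of 17871 tested genes were called between the genotypes, 1765 higher and 1144 lower in KO, and 856 of them had an absolute log2 fold change of at least 0.58. Besides the genes above, the 10 highest included Lonrf3 (log2 fold change 2.94, SE 0.27, edgeR adjusted p = 2.16e-09), the clock repressor Ciart (2.84, SE 0.11), Tpbgl (2.64, SE 0.17), the netrin receptor Unc5c (2.06, SE 0.17) and the histamine receptor Hrh3 (1.85, SE 0.18). The 10 lowest were Fabp7 (log2 fold change −4.32, SE 0.25, edgeR adjusted p = 3.77e-14), the securin Pttg1 (−3.40, SE 0.61), Hcls1 (−2.21, SE 0.10), the collagen Col5a3 (−2.06, SE 0.17), and Gdpd3 (−1.80, SE 0.51), followed by others with smaller changes. These were the clock repressor Nfil3 (−1.45, SE 0.09), Dock8 (−1.42, SE 0.14), the axonemal dynein Dnah9 (−1.40, SE 0.17), Fscn2 (−1.37, SE 0.08) and Ccdc63 (−1.33, SE 0.10). Pttg1 varied widely within each genotype, from 0.221 to 19.6 CPM in WT and from 0.0829 to 11.3 CPM in KO. Some of these genes lie on the chromosomes of the targeted loci: Col4a3 on chromosome 1 (82586921 to 82722059), and Dnah9 (65831282 to 66168551), Rasl10b (83409137 to 83421039), Pttg1 (43420250 to 43426251) and Fscn2 (120361534 to 120368168) on chromosome 11. With the level of inner retinal markers as a covariate 860 genes were called, 697 of them among the 2909, and Gdpd3 was no longer called. At single times, different sets of libraries gave 2598 genes called at any time, and 86 were called in the same direction at all 4, of which 69 were higher and 17 lower in KO. Another 2 were called at all 4 times with both directions.

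Core clock genes had the smallest camera p of the lists. Of 24 tested members 17 were called, 14 higher and 3 lower in KO, and 19 passed when adjusted over the list alone (camera adjusted p = 3.72e-56, and adjusted p = 1.46e-08 with an estimated correlation). The D-box activators rose together: Dbp from 40.6 ± 7.42 to 143 ± 14.1 CPM (log2 fold change 1.83, SE 0.06), Tef from 189 ± 12.6 to 427 ± 21.3 CPM (1.17, SE 0.04) and Hlf by 1.20 (SE 0.06), with edgeR adjusted p = 7.17e-20, 3.62e-21 and 1.31e-16. Among repressors, Ciart, Per2, Per3 (1.26, SE 0.09), Cry2 (1.20, SE 0.04), Bhlhe40 (1.06, SE 0.12), Bhlhe41 (0.82, SE 0.05), Per1 and Cry1 (0.46, SE 0.04) rose, as did Nr1d2 (0.72, SE 0.04) and Nr1d1 (0.68, SE 0.05). Arntl, which encodes the activator BMAL1, fell from 159 ± 7.47 to 94.7 ± 4.76 CPM (log2 fold change −0.74, SE 0.03, edgeR adjusted p = 9.92e-18), and Nfil3 fell by 1.45. The other 7 members were not called: Csnk1e (0.06), Rorb (−0.02), Rora (−0.06), Clock (−0.09), Csnk1d (−0.09), Npas2 (−0.21) and Fbxl21 (−0.35). At single times 15 members were called at CT19, 14 at CT22, 14 at CT1 and 17 at CT10, and 16 of the 17 remained called with the inner retina covariate.

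**Figure D2:**
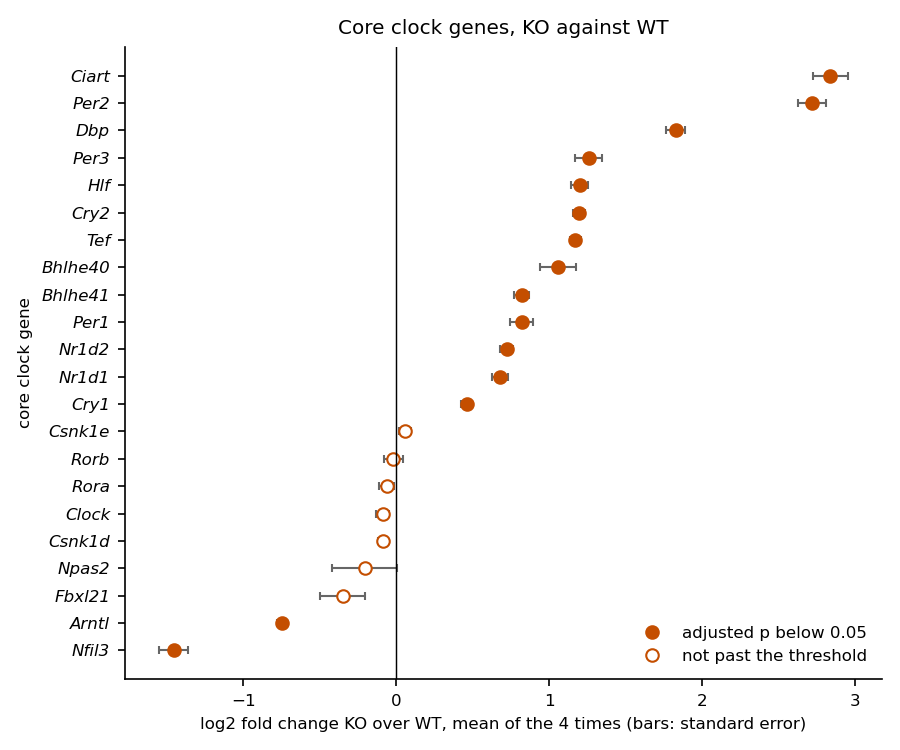
Log2 fold change of KO over WT (mean of the 4 times, bars are standard errors, 16 libraries of each genotype) for core clock genes, with filled points for called genes. Ciart (2.84) and Per2 (2.72) lay highest, and Nfil3 (−1.45) and Arntl (−0.74) lowest.

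Photoreceptor lists shifted slightly downward in KO, in the same contrast in which bipolar (10 of 14, median 0.50) and Müller glia markers (6 of 14, median 0.38) rose. Of 21 rod phototransduction genes 8 fell and 1 rose (11 called when adjusted over the list alone), with Guca1b, an activator of guanylate cyclase, at −0.43 (SE 0.08), Rgs9bp at −0.25 (SE 0.05), Gnb5 at −0.24 (SE 0.04) and the phosphodiesterase subunit Pde6b at −0.21 (SE 0.04). This list had camera adjusted p = 3.64e-05, and adjusted p = 0.424 with an estimated correlation. Among 13 cone phototransduction genes 5 fell, including Pde6h (−0.50, SE 0.15), Kcne2 (−0.31, SE 0.08) and the cone opsin Opn1mw (−0.26, SE 0.08), while the channel subunit Cngb3 rose by 0.34 (SE 0.06). Adjusted over the list alone 7 were called, and camera gave adjusted p = 0.0324, and adjusted p = 0.518 with an estimated correlation. Of 24 genes of outer segment structure 4 fell (7 adjusted over the list alone): Fscn2, the retinol dehydrogenases Rdh8 (−0.30, SE 0.04) and Rdh12 (−0.16, SE 0.04), and the kinase Mak (−0.19, SE 0.05). Outer segment genes had camera adjusted p = 1.95e-04 and adjusted p = 0.424 with an estimated correlation.

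Genes of phosphatidylserine exposure and photoreceptor phagocytosis showed few differences between the genotypes. Of 34 tested members 3 rose in KO and none fell, and the same number was called when adjusted over the list alone (camera adjusted p = 0.973). They were the phospholipid flippase Atp11a (0.32, SE 0.05, edgeR adjusted p = 3.31e-05), the chemokine Cx3cl1 (0.63, SE 0.16, adjusted p = 0.00719) and the integrin subunit Itgb5 (0.24, SE 0.07, adjusted p = 0.0124). The receptor Tyro3 stood at −0.97 (SE 0.34, edgeR adjusted p = 0.0557). By time, 1 member was called at CT19 (Itgb5, 0.62, SE 0.14), 0 at CT22, 1 at CT1 (Atp11a, 0.57, SE 0.10) and 3 at CT10 (Cx3cl1, Axl and Atp11a).

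Metabolic and signalling lists were mixed. In the fatty acid list 8 of 24 genes fell and 4 rose (14 called when adjusted over the list alone). The lower ones included Fads2 (−0.44, SE 0.08), Acaca (−0.35, SE 0.07), Elovl2 (−0.27, SE 0.04) and Agpat3 (−0.25, SE 0.04), enzymes of fatty acid synthesis, desaturation and elongation and of phospholipid acylation. Camera gave adjusted p = 0.00579, and adjusted p = 0.424 with an estimated correlation. Dopamine, melatonin and cAMP genes included 8 of 14 that rose and none that fell (8 adjusted over the list alone), led by Pde4b (0.50, SE 0.09), Prkar1b (0.42, SE 0.09) and the dopamine receptors Drd1 (0.71, SE 0.17) and Drd2 (0.51, SE 0.13). They had camera adjusted p = 0.00434 and adjusted p = 0.424 with an estimated correlation. None of these 8 stayed called with the inner retina covariate. Glycolysis genes went both ways, 4 up and 3 down of 19 (10 adjusted over the list alone, camera adjusted p = 0.932, with a median of −0.00 and a mean of 0.00 that differed in sign). Higher were Pfkm (0.39, SE 0.06) and Bsg (0.30, SE 0.05), and lower were Slc2a1 (−0.22, SE 0.05) and Hk1 (−0.21, SE 0.05). Of 11 tested mitochondrially encoded genes 0 were called by edgeR over all genes or over the list alone (camera adjusted p = 0.960). Single members of other lists changed too: Wee1, a cell cycle kinase, rose by 1.01 (SE 0.18), the synaptic adhesion gene Elfn2 by 0.69 (SE 0.08) and the endoplasmic reticulum stress gene Herpud1 by 0.50 (SE 0.06).

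Over the mean of the 4 times, markers of other retinal cells were higher in KO, but unevenly over the times. The inner retina level (bipolar, amacrine and Müller markers, mean log2 CPM) was 4.02 in WT against 4.49 in KO at CT19. At CT10 it was 3.32 against 4.28, at CT22 4.28 against 4.36 and at CT1 3.80 against 3.99. Amacrine markers were not higher in KO at CT22 (2.79 against 2.88 in WT) or at CT1 (2.36 against 2.40). Of 14 bipolar cell markers 10 rose and none fell (11 adjusted over the list alone). Nyx rose from 2.94 ± 0.766 to 8.82 ± 1.52 CPM, a log2 fold change of 1.60 (SE 0.10). Bipolar markers had camera adjusted p = 1.07e-08, and adjusted p = 0.424 with an estimated correlation. Of 14 Müller glia markers 6 rose (10 adjusted over the list alone), among them the potassium channel Kcnj10 (0.67, SE 0.10) and glutamine synthetase Glul (0.41, SE 0.12). Müller markers had camera adjusted p = 2.53e-04 and adjusted p = 0.518 with an estimated correlation. Amacrine markers included 5 of 12 that rose (5 adjusted over the list alone, camera adjusted p = 0.0111, and adjusted p = 0.519 with an estimated correlation). Of horizontal cell markers 5 of 8 rose (5 adjusted over the list alone, camera adjusted p = 0.00216, and adjusted p = 0.424 with an estimated correlation). For the pigment epithelium, 1 of 16 markers (Ezr, 0.63, SE 0.21) was called over all genes and 0 over the list alone (camera adjusted p = 0.827), and the list's median (−0.02) and mean (0.06) differed in sign. Lens markers varied most between libraries: Bfsp2 alone of 15 was called (−2.37, SE 0.73), 0 over the list alone, and the list had camera adjusted p = 0.00434, and adjusted p = 0.651 with an estimated correlation.

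At CT19 the genotypes differed in 928 genes, 516 higher and 412 lower in KO. The extremes were Lonrf3 (log2 fold change 3.24, SE 0.54), Col4a3 (3.19, SE 0.26) and Ciart (3.06, SE 0.23) on the high side, and Pttg1 (−4.85, SE 1.30), Fabp7 (−4.56, SE 0.51) and Hcls1 (−2.24, SE 0.20) on the low side. Pttg1 was not called with the inner retina covariate, alone or together with the lens level. Among photoreceptor genes the calcium sensor Rcvrn fell by 0.52 (SE 0.14), Rdh8 by 0.50 (SE 0.09) and Fscn2 by 1.25 (SE 0.16), and Cngb3 rose by 0.65 (SE 0.13). The count at CT19 rested on few libraries: it was 423 without WT replicate 3, 513 without KO replicate 2, 514 without KO replicate 3 and 562 without KO replicate 4.

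At CT22 the count was 273 (161 higher, 112 lower in KO), with Akap5 (3.08, SE 0.23), Col4a3 (2.99, SE 0.26) and Ciart (2.98, SE 0.23) highest and Fabp7 (−4.76, SE 0.51), Hcls1 (−2.25, SE 0.20) and Col5a3 (−2.16, SE 0.35) lowest. Apart from the clock list, few list members were called there: Fscn2 (−1.16, SE 0.15), Agpat3 (−0.36, SE 0.09), Elovl2 (−0.33, SE 0.08), Wipi1 (−0.33, SE 0.08), Lss (0.27, SE 0.07) and Nyx (1.28, SE 0.20). Leaving out WT replicate 3, WT replicate 6, KO replicate 2 or KO replicate 3 of CT22 gave 179, 180, 179 and 170 genes.

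At CT1 282 genes were called (190 higher, 92 lower in KO). Highest were Col4a3 (3.37, SE 0.26), Lonrf3 (3.32, SE 0.53) and Akap5 (3.14, SE 0.23), and lowest Fabp7 (−4.26, SE 0.49), Col5a3 (−2.05, SE 0.34) and Hcls1 (−1.89, SE 0.20). List members called at CT1 outside the clock included Fscn2 (−1.57, SE 0.16), Gnb5 (−0.28, SE 0.07), Pcdh15 (0.86, SE 0.22), Ddit4 (−0.42, SE 0.10), Elfn2 (0.85, SE 0.16) and Nyx (1.68, SE 0.21).

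CT10 held the most differences of the 4 times, with 1825 genes called (1286 higher, 539 lower in KO) and 1339 with an absolute log2 fold change of at least 0.58. CT10 went from the most to the fewest with the inner retina covariate, which gave 247 genes at CT10 against 422 at CT19, 289 at CT22 and 322 at CT1, and with the lens level added (72 against 389, 298 and 251). Dopamine, melatonin and cAMP genes rose in KO at this time: 10 of 14 rose and 1 fell (13 adjusted over the list alone). Among them were the dopamine receptors Drd4 (329 ± 29.6 CPM in WT against 580 ± 102 in KO, SD, n = 4, log2 fold change 0.82, SE 0.11) and Drd2 (1.43, SE 0.27), the adenylyl cyclase Adcy8 (1.97, SE 0.36) and Prkar1b (0.99, SE 0.19). This list had camera adjusted p = 3.70e-10, and adjusted p = 0.0157 with an estimated correlation. Immediate early genes included 5 of 16 that rose and 1 that fell (7 adjusted over the list alone). Nr4a1 stood at 21.2 ± 1.95 CPM in WT and 61.1 ± 15.4 in KO (1.52, SE 0.24), and Fos (1.34, SE 0.34), Junb (0.78, SE 0.17) and Dusp1 (0.71, SE 0.19) were also higher. These genes had camera adjusted p = 0.00557, and adjusted p = 0.288 with an estimated correlation. Acadm and Cpt1a, enzymes of fatty acid oxidation, were lower in KO, Acadm by 0.97 (129 ± 19.5 CPM in WT, 65.7 ± 7.34 in KO) and Cpt1a at −0.84 (SE 0.13). The elongase Elovl2 was lower too (−0.34, SE 0.08), which made 3 of 24 in that list (6 adjusted over the list alone). The phagocytosis list had Cx3cl1 (1.43, SE 0.33), the receptor Axl (1.24, SE 0.33) and Atp11a (0.32, SE 0.10) among its called members (3 of 34, 3 adjusted over the list alone, camera adjusted p = 0.622). With the inner retina covariate Axl (−0.03) and Cx3cl1 (0.15) were no longer called, and with the lens level added Cx3cl1 stood at −0.085 and none of the 3 was called. Of the unfolded protein list 4 of 20 rose (4 adjusted over the list alone): Herpud1 (0.83, SE 0.12), Sdf2l1 (0.60, SE 0.17), Xbp1 (0.49, SE 0.15) and Manf (0.43, SE 0.13), with camera adjusted p = 0.0137, and adjusted p = 0.390 with an estimated correlation.

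The extremes at CT10 were Tpbgl (log2 fold change 4.53, SE 0.39), Lonrf3 (3.55, SE 0.55) and Per2 (3.26, SE 0.19) on the high side and the lens filament gene Bfsp2 (−5.74, SE 1.66), Fabp7 (−3.68, SE 0.50) and the kinesin Kif4 (−2.79, SE 0.41) on the low side. Lonrf3 and Bfsp2 were not called with the inner retina covariate, Bfsp2 not with the lens covariate, and Lonrf3, Bfsp2 and Kif4 not with both. Marker levels moved with this contrast. Mean log2 CPM of the bipolar markers was 3.81 ± 0.43 in WT at CT10 against 5.08 ± 0.21 in KO (SD, n = 4), that of Müller glia 4.39 ± 0.39 against 5.21 ± 0.22 and that of lens markers 7.46 ± 0.90 against 4.89 ± 1.54. Of the bipolar list 11 of 14 rose (11 adjusted over the list alone), including Grm6 (1.99, SE 0.35) and Cabp5 (1.45, SE 0.25). At CT10 this list had camera adjusted p = 5.09e-15, and adjusted p = 0.1003 with an estimated correlation. With the inner retina level as a covariate, 2 of the 11 dopamine and cAMP genes and 1 of the 6 immediate early genes stayed called. The count was 946 without WT replicate 2, 1210 without WT replicate 4 and 1037 without KO replicate 4 of CT10.

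**Figure D3:**
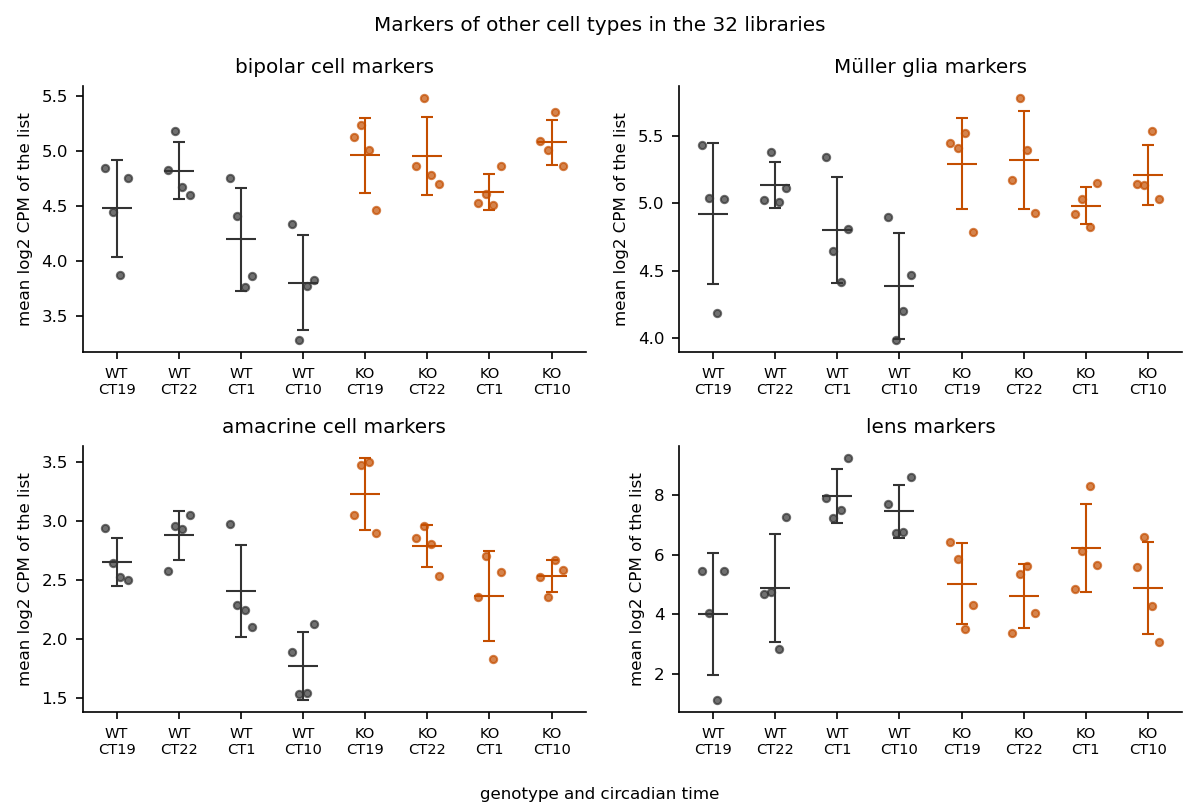
Mean log2 CPM of marker lists of other cell types in the 32 libraries by genotype and circadian time, with points for libraries and bars for the mean and SD of 4. Bipolar markers averaged 3.81 in WT at CT10 and 5.08 in KO at CT10, and lens markers ranged in group mean from 4.02 in WT at CT19 to 7.98 in WT at CT1.

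Pairs of times compared different libraries, but all contrasts came from the same fit and shared each gene's estimate of spread. The called lists are therefore not independent. The numbers given for independent lists are only a rough reference, and an overlap above them can come in part from the shared estimate. CT19 and CT22 shared 114 genes higher in KO (4.65 for independent lists) and 65 lower (2.58), with 0 in opposite directions by the same edgeR test. CT1 and CT10 shared 121 higher (13.7 for independent lists) and 34 lower (2.77), with 2 opposite. CT19 and CT10 shared 193 higher (37.1) and 54 lower (12.4), and 41 genes went in opposite directions at these times.

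The next comparison asked which transcripts changed over the 4 times within WT. Acadm, the medium-chain acyl-CoA dehydrogenase of fatty acid oxidation, stood at 55.5 ± 3.26, 56.8 ± 3.69 and 65.5 ± 7.37 CPM at CT19, CT22 and CT1 and at 129 ± 19.5 CPM at CT10 (SD, n = 4 each). Drd4, the dopamine receptor of photoreceptors, had the opposite course, with 820 ± 58.2, 697 ± 31.7 and 717 ± 95.6 CPM at CT19, CT22 and CT1 and 329 ± 29.6 at CT10. Nr4a1, an immediate early nuclear receptor, went from 110.5 ± 10.8, 124 ± 20.6 and 82.8 ± 25.8 CPM to 21.2 ± 1.95, and Dip2b from 154 ± 8.84, 153 ± 6.87 and 136 ± 11.4 CPM to 77 ± 4.57.

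In WT 2615 genes were called for time, and CT10 stood farthest from the other times in 2122 of them. At CT10, 1250 were highest and 1246 lowest. The times are unevenly spaced, with CT19, CT22 and CT1 close together and CT10 far from them. A smooth daily rhythm can therefore set CT10 apart through the sampling alone. The 12 smallest p-values included those of Acadm (range 1.21 in log2 units) and Drd4 (1.32), both with edgeR adjusted p = 2.1e-08. Also among them were Pdzph1 (1.41), Dnajb2 (0.87), Rims2 (0.96), Rgs20 (1.11), Ntm (0.78), Utp20 (1.14), E2f3 (1.04), Dip2b (0.997) and Plekhb1 (1.11, edgeR adjusted p = 3.42e-07). Higher at CT10 than at the other times were Acadm, Pdzph1, the regulator of G protein signalling Rgs20, Ntm, Utp20 and the vesicle release gene Rims2 (486 ± 52.0 CPM at CT10, 250.3 ± 23.9 at CT19). The chaperone Dnajb2, the cell cycle factor E2f3, Dip2b, Drd4 and Plekhb1 (1001.3 ± 66.6 CPM at CT10, 2166 ± 316 at CT19) were lower there. Without the CT10 libraries, the time test in WT called 0 genes by edgeR, over times that lie close together. Leaving out WT replicate 2 of CT10 left 1563.

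**Figure D4:**
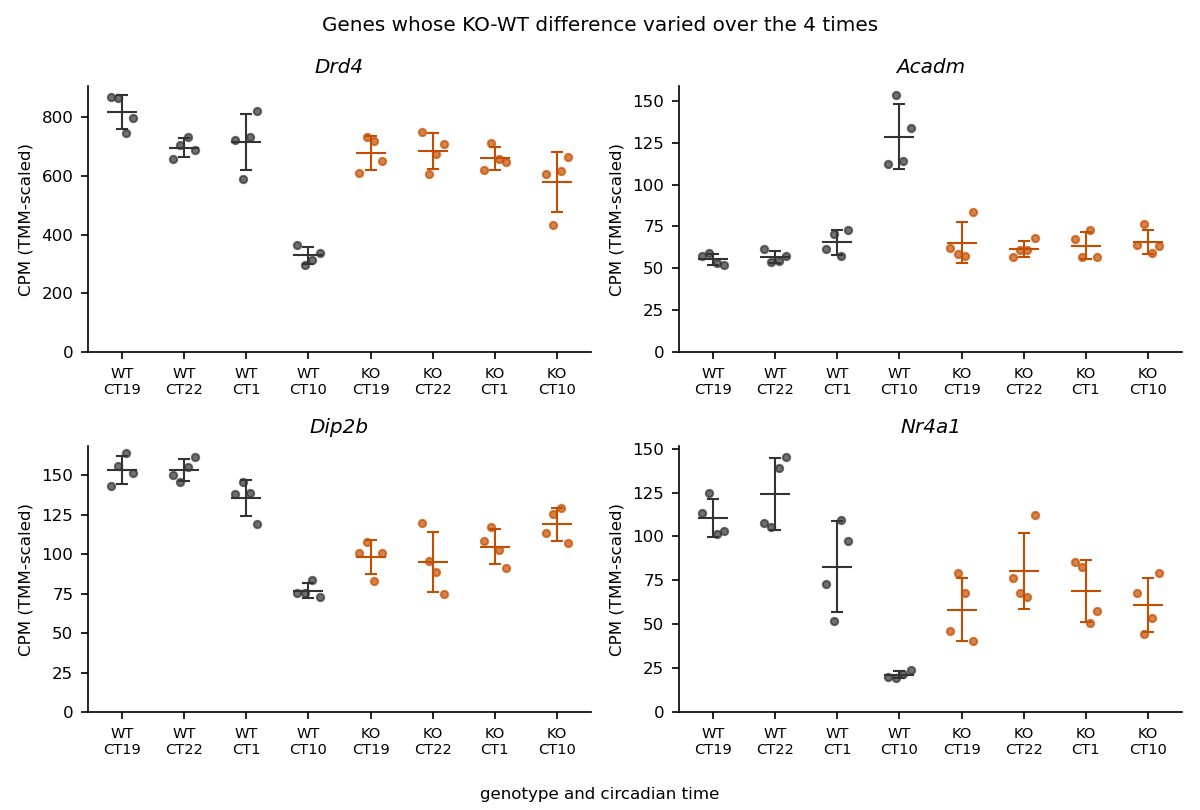
Normalised expression (CPM, TMM-scaled) of Acadm, Drd4, Dip2b and Nr4a1 in the 32 libraries by genotype and circadian time, with points for libraries and bars for the mean and SD of 4. In WT, Acadm rose to 129 CPM at CT10 while Drd4 (329), Dip2b (77) and Nr4a1 (21.2) were lowest there.

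By list, time in WT was called for 10 of 14 dopamine, melatonin and cAMP genes (11 adjusted over the list alone). They included the phosphodiesterase Pde10a (range 2.45, 13.97 ± 4.15 CPM at CT19, 3.61 ± 0.551 at CT10), the cyclase Adcy1 (0.95, highest at CT10 with 734 ± 66.2 CPM) and the G protein Gnaz (0.81). CPM values beside a range are for chosen times, and for Pde10a, and for Sag below, they are not the pair that makes the range. Immediate early genes had 7 of 16 (9 adjusted over the list alone), with Nr4a1 (2.55), Dusp1 (1.23), Junb (1.14) and Ier2 (1.03). Of the synapse list 7 of 24 were called (9 adjusted over the list alone), with Rims1 (1.08), Rims2 (0.96), Syt1 (0.67) and Cabp4 (0.34). Rod phototransduction had 4 of 21 (7 adjusted over the list alone): Rcvrn (0.93, 2671 ± 209 CPM at CT19, 1402 ± 103 at CT10), the rod arrestin Sag (0.80, 6147 ± 220 at CT19, 9281 ± 2685 at CT10), Guca1b (0.55) and Gnb5 (0.28). In the phagocytosis list 3 of 34 were called (3 adjusted over the list alone): Cx3cl1 (1.52), Axl (1.27) and the bridging ligand Gas6 (0.34, 310 ± 25.5 CPM at CT1, 246 ± 21.7 at CT10). Fatty acid genes had 3 of 24 (3 adjusted over the list alone), Acadm, Cpt1a (0.63) and Elovl6 (0.49). Markers moved too, with 10 of 12 amacrine (11 adjusted over the list alone), 7 of 14 bipolar (12) and 7 of 15 lens markers (15) called. With the inner retina covariate 1536 genes were called, the 12 genes with the smallest p among them, and with inner retina and lens levels together 494, again with all 12.

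Of the 24 core clock genes 6 were called for time in WT (9 adjusted over the list alone), including Cry2 (range 0.39, edgeR adjusted p = 0.00465), Per2 (0.78), Bhlhe40 (1.04), Csnk1e (0.34) and Rorb (0.54). Cry2 stood at 75.3 ± 3.0 CPM at CT22 and 57.5 ± 5.45 at CT10. Arntl had a range of 0.06 (edgeR adjusted p = 0.853), with 163, 157, 156 and 159 CPM at CT19, CT22, CT1 and CT10, and Per1 (0.37), Dbp (0.43), Nfil3 (0.66) and Nr1d1 (0.21) were not called by edgeR's F test. A cosine curve of 24 h called Dbp (edgeR adjusted p = 0.0272), Nfil3 (0.0356) and Nr1d2 (0.0328) in WT.

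In KO the same test called a single gene by edgeR, Csdc2, an RNA-binding cold-shock domain protein, at 12.8 ± 4.02 CPM at CT19, 7.43 ± 1.54 at CT22, 5.04 ± 0.786 at CT1 and 6.80 ± 0.619 at CT10 (range 1.34, edgeR adjusted p = 0.0257). At an unadjusted p under 0.05 there were 1862 genes in KO against 5252 in WT, and DESeq2 called 203 and limma voom 268 genes for time in KO. Over the 2615 genes called for time in WT, the median range was 0.63 in WT and 0.24 in KO, a comparison in which the genes were chosen for their change in WT. Over all 17871 tested genes it was 0.39 in WT and 0.28 in KO. Adjusted over the list alone, 9 of 11 mitochondrially encoded genes, 8 of 12 amacrine markers and 7 of 24 outer segment genes were called for time in KO, and 0 of these over all genes. No core clock gene was called for time in KO, over all genes or over the list alone. Leaving out KO replicate 5 of CT19 gave 29 genes, and leaving out KO replicate 3 or 4 of CT19 or KO replicate 1, 5 or 6 of CT1 gave 0.

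Whether the genotype difference itself varied over the 4 times was tested as an interaction. Dip2b was lower in KO at CT19 (log2 fold change −0.65, SE 0.10), CT22 (−0.69, SE 0.10) and CT1 (−0.37, SE 0.10) and higher at CT10 (0.63, SE 0.10), and Nr4a1 went from −0.92 (SE 0.23) at CT19 to 1.52 (SE 0.24) at CT10. Acadm differed by 0.24 (SE 0.11) at CT19 and −0.97 (SE 0.11) at CT10, and Drd4 by −0.27 (SE 0.11) and 0.82 (SE 0.11). In KO the group means lay between 61.7 and 65.7 CPM for Acadm, 580 and 686 for Drd4, 58.3 and 80.4 for Nr4a1, and 94.9 (CT22) and 119 (CT10) for Dip2b.

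The interaction was called for 289 genes, and 281 of these were also among the genes called for time in WT, a share that the common WT libraries raise. CT10 stood farthest from the other times in 254 of the 289, and the uneven spacing of the times can set it apart here too. The 12 smallest p-values included those of Dip2b (edgeR adjusted p = 9.94e-06), E2f3, Pdzph1, Acadm, the translation inhibitor Pdcd4, Dnajb2, Drd4, the deubiquitinase Usp29, the secreted glycoprotein Olfm1, Nr4a1 and the histone deacetylase Hdac9 (adjusted p = 4.92e-04). By list, 6 of 14 dopamine and cAMP genes (9 adjusted over the list alone), 3 of 16 immediate early genes (5), 2 of 24 synapse genes (2), 2 of 24 fatty acid genes (2) and 0 of 34 phagocytosis genes (0, by edgeR) were called. Of the core clock only Rorb, a nuclear receptor of photoreceptors, was called over all genes (range 0.77, edgeR adjusted p = 0.0154), with 2 adjusted over the list alone. Without the CT10 libraries 0 interaction genes were called by edgeR, and with inner retina and lens levels as covariates 11, among which 5 of the 12 genes with the smallest p. The count was 155 and 173 without WT replicates 2 and 5 of CT10, and 169, 142 and 161 without KO replicates 2, 4 and 5 of CT10.

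**Figure D5:**
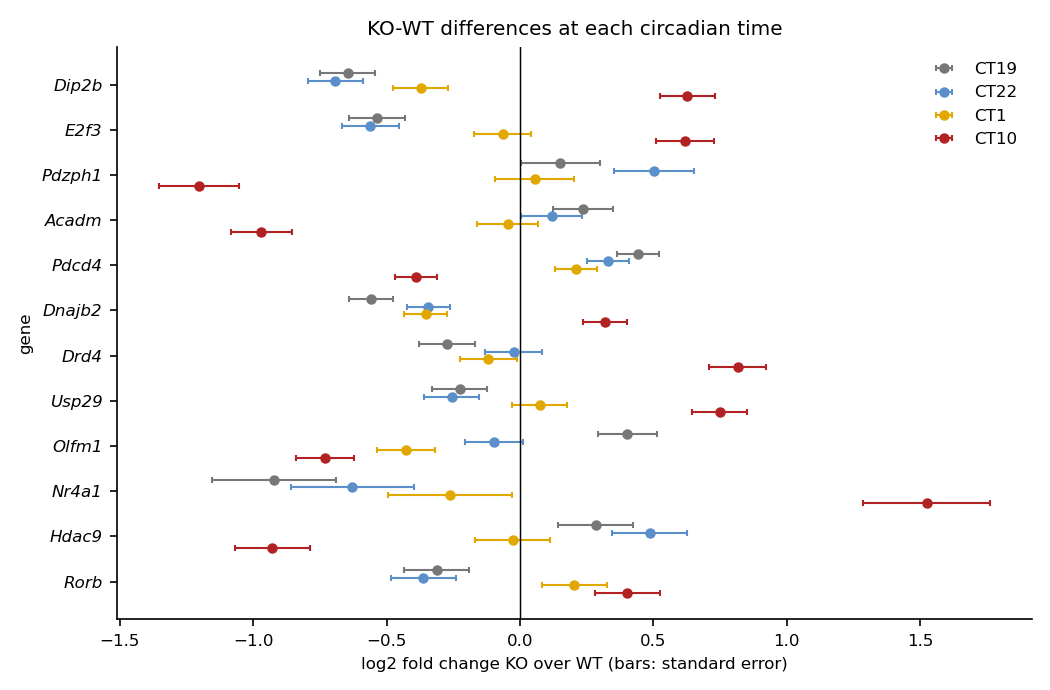
Log2 fold change of KO over WT at each circadian time (4 libraries against 4, bars are standard errors) for genes with a called interaction. Dip2b moved from −0.65 at CT19 to 0.63 at CT10, and Acadm from 0.24 to −0.97.

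The last comparison set CT1, the sampled time nearest to the known morning peak of outer segment phagocytosis, against the mean of the other 3 times. In both genotypes 0 genes were called by edgeR, with 1347 genes in WT and 1619 in KO at an unadjusted p under 0.05; DESeq2 called 2 and 36, and limma voom 0 and 158. In the phagocytosis list 0 of 34 members passed in WT or in KO, over all genes or when adjusted over the list alone, with camera adjusted p = 0.502 in WT and 0.576 in KO, where the median (0.02) and the mean (−0.09) differed in sign. Among its smallest p-values in WT was that of Atp11a (−0.22, SE 0.08, edgeR adjusted p = 0.640), with Gas6 at 0.15 (SE 0.07) and Mfge8 at 0.20 (SE 0.10). In KO they were those of Plscr1 (−1.12, SE 0.34, edgeR adjusted p = 0.351), Anxa5 (−0.68, SE 0.23) and Rac1 (−0.19, SE 0.07). Camera called 7 lists at CT1 in WT and 14 in KO, of which a few are given here. In WT they included lens markers (median 2.18, 15 of 15 adjusted over the list alone, camera adjusted p = 3.06e-27, and adjusted p = 0.123 with an estimated correlation). Nuclear oxidative phosphorylation genes were called as well (median 0.16, 0 of 74 adjusted over the list alone, camera adjusted p = 2.10e-12, and adjusted p = 0.794 with an estimated correlation). In KO they included mitochondrially encoded genes (median 0.53, 10 of 11 adjusted over the list alone, camera adjusted p = 6.20e-14, and adjusted p = 0.173 with an estimated correlation). Amacrine markers were lower there (median −0.45, 7 of 12 adjusted over the list alone, camera adjusted p = 4.12e-08, and adjusted p = 0.173 with an estimated correlation). Rod phototransduction genes were higher (median 0.17, 5 of 21 adjusted over the list alone, camera adjusted p = 9.76e-10, and adjusted p = 0.202 with an estimated correlation). On simulated counts the test at CT1 in WT found 58.2% of genes changed 1.5-fold, so changes of that size could be missed.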

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

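All counts over other splits of the libraries, the test of how many genes stayed called with the inner retina covariate, and the slopes within KO for the genes highest at CT10, were chosen after the results were seen.

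The genotype difference varied over the 4 times in 289 genes by edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment, which is what singled out the following genes. Adjusted p-values for this difference between times were 9.94e-06 for Dip2b, 1.09e-04 for E2f3, 1.73e-04 for Pdzph1, 2.45e-04 for Acadm, 2.75e-04 for Pdcd4 and Dnajb2, 3.77e-04 for Drd4, 4.69e-04 for Usp29, Olfm1 and Nr4a1, 4.92e-04 for Hdac9 and, for the core clock gene Rorb, 0.0154. Among 80 splits that exchanged genotypes within times, 2 gave as many interaction genes, the real one (289) and one with 526. The 3 other splits with the highest counts (526, 182 and 83) were those that kept the CT10 libraries apart by genotype, and the highest of the remaining splits gave 1. The count thus went with the CT10 libraries being apart by genotype, and among such splits the real one was not the highest. Exchanging genotypes also adds the genotype difference to the spread within groups, so the splits do not decide whether the count needs the real genotypes at the other times.

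For time in WT, 1 of the 80 splits, the real one, reached the count of 2615 genes. The highest of the other 79 splits gave 328, which argues against chance. These genes set CT10 apart from the other 3 times, and the WT CT10 libraries had inner retinal markers lower by 0.71 log2 units and a high lens level. At CT1, where lens markers were as high, these genes had moved by 28.3% of their CT10 shift. This met the limit set beforehand against lens RNA, but choosing genes highest or lowest at CT10 lowers the share by construction. Lens RNA therefore stays open for them. For the genes highest at CT10, the median rise of 0.41 lay below the 95th percentile of rod phototransduction genes (0.45, with a median of 0.03). By the rule set beforehand, this result went with a lower share of other retinal cells. Slopes on the inner retina level within KO, a test added afterwards, predicted −0.323% of their rise (−4.01% to 3.17% without single KO libraries). The tests disagree, so a lower share of other retinal cells stays open for these genes. For the genes lowest at CT10, the same slopes predicted 25.3% of the fall (22.1% to 32.7%), between the limits set for either answer, so a part of that fall may come from fewer inner retinal cells in the captured tissue. A biological difference at CT10 that is absent in KO stays open and was not tested further. It need not be particular to CT10, since the uneven spacing of the times lets a smooth daily rhythm set that time apart.

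For KO against WT over the mean of the times, 1 of 80 splits, the real one, reached the count of 2909 genes. The highest other split gave 4, which argues against chance. These genes went with higher inner retinal markers in KO. Of them 24.0% stayed called with the inner retina covariate. The 17 called core clock genes kept a median of 97.5% of their fold, which argues against a share of other cells as the source of their calls. The other genes that stayed called were chosen by keeping their call, so for them a share of other cells is not excluded. The genes no longer called kept 43.0% of their median log2 fold (0.39 before and 0.17 after), but they were chosen by losing their call, so for them a larger share of inner retinal cells in KO cannot be told apart from an effect of the genotype. Within the segments linked to the targeted loci lay 2.1% of the called genes. These segments held 193 and 109 of the 17871 tested genes, too few to be the source of most of the 2909 calls whatever the share. Wider linked segments were not tested. Outside them, the fullest window of 100 neighbouring tested genes held 13 strongly changed genes against a median of 13 in random orders (permutation p = 0.602 over 1000 random orders). By the rule set beforehand this went against other segments of different descent. It shows no dense cluster of strongly changed genes, but short or scattered segments need not raise the fullest window, so different descent is not excluded. For the called genes inside the linked segments, linkage cannot be told apart from the genotype: the odds ratio of a call was 1.31 (95% interval 0.968 to 1.74, Fisher exact p = 0.0702), with 45 of 193 genes called around Per1 and 16 of 109 around Per2. An effect of the missing Per function stays open for the genes kept with the covariate, as does linkage for Dnah9, which lies inside the segment around Per1. Col4a3, Rasl10b, Pttg1 and Fscn2 lie outside the linked segments but on the same chromosomes as the targeted loci. With wider segments untested, linkage is not excluded for these genes either.

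At single times chance is argued against too, with 1 of 35 splits reaching the count each time, the smallest number possible. The counts were 928 at CT19 and 273 at CT22, against 124 and 2 in the highest other splits. At CT1 and CT10 they were 282 and 1825, against 21 and 1. Chance is not excluded for time in KO, where 5 of 80 splits gave at least the 1 gene called (highest other 2). For CT1 against the other times the splits decide nothing, since with 0 genes called all 80 reach the count. The highest other splits there gave 597 genes in WT and 234 in KO, values that point to a structure of the samples.

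Single libraries stood far from the other 3 of their group in 10 of 168 groups tested, where chance gives about 8.4. In WT at CT1, replicate 4 had 143 CPM of Per1 (others 94.4 to 101) and 44.3 CPM of Per2 (others 24.9 to 27.8). Per2 was 169 CPM in KO replicate 5 of CT1 (others 204 to 206) and 184 CPM in KO replicate 3 of CT10 (others 207 to 209.8), where the mean log2 CPM of the core clock list was also low, at 6.13 (others 6.16 to 6.17). Arntl stood at 165 CPM in WT replicate 1 of CT22 (others 154 to 155) and at 154 CPM in WT replicate 4 of CT10 (others 159.9 to 161). Fabp7 stood at 1.63 CPM in WT replicate 1 of CT10 (others 3.21 to 3.5). At CT19 in KO, rod phototransduction genes averaged 11.18 log2 CPM in replicate 3 (others 11.36 to 11.39) and Müller glia markers 4.79 in replicate 5 (others 5.41 to 5.52).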

How the results depend on the processing

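Among the alternatives, the lens covariate, the inner retina and lens covariates together and the fit without CT10 were chosen after the data were seen. The cause of the shifts below was not tested, except that a fold limit, an adjusted p under 0.1 and fewer libraries change counts by construction.

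Over the mean of the times, KO against WT gave 860 genes with the inner retina covariate, 637 with the lens level added, 856 with an absolute log2 fold change of at least 0.58 and 1695 without CT10, against 2909. At CT19 (928) DESeq2 gave 1501, no filter 546, only the libraries compared 194, the inner retina covariate 422, both covariates 389, an adjusted p under 0.1 1703 and the fold limit 444. At CT22 (273) DESeq2 gave 454, limma voom 632, only the libraries compared 120, an adjusted p under 0.1 414 and the fold limit 161, and at CT1 (282) DESeq2 gave 486, only the libraries compared 180, an adjusted p under 0.1 459 and the fold limit 182. At CT10 (1825) voom gave 3256, the inner retina covariate 247 and both covariates 72. Time in WT (2615) gave 1656 with its own libraries only, 1536 with the inner retina covariate, 494 with both covariates, 1415 with the fold limit and 0 without CT10. Time in KO (1) gave 203 by DESeq2, 268 by voom, 5 without a filter, 3 at an adjusted p under 0.1, 14 by the cosine curve, 2 without CT10, and 0 with the set of 8 libraries as a term, with its own libraries only, with the inner retina covariate or with both covariates. The interaction (289) gave 955 by DESeq2, 725 by voom, 624 at an adjusted p under 0.1, 561 by the cosine curve, 178 with the inner retina covariate, 131 with the lens covariate, 11 with both and 0 without CT10. CT1 against the other times gave 2 genes in WT by DESeq2, and 36 in KO by DESeq2 and 158 by voom.

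Of the gene lists, camera at the preset correlation called 17 for the mean, 13, 8, 9 and 17 at CT19, CT22, CT1 and CT10, and 7 in WT and 14 in KO for CT1 against the other times. With an estimated correlation these were 1, 1, 1, 1 and 2, and 0 in WT and 0 in KO. By fry they were 2 at CT19, 1 at CT22, 1 at CT1, 0 in WT and 0 in KO. Over all contrasts fry left 169 list results the same, called or not, while 53 were no longer called and 2 were newly called. Fry thus kept calls for the mean and at CT10, whose counts are not given here. The core clock list was called with an estimated correlation in every KO against WT comparison, and the dopamine, melatonin and cAMP list at CT10.

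Replicate numbers did not pair the libraries: 3 of 12 same-numbered pairs had a correlation of deviations over 0.1 (−0.101 to 0.2097). With a replicate block the counts were 3069 for the mean, 844, 215, 254 and 1963 at CT19, CT22, CT1 and CT10, 2237 for time in WT, 0 for time in KO and 308 for the interaction.

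Leaving out each library in turn gave 2456 to 3278 genes for the mean, 423 to 1164 at CT19, 170 to 295 at CT22, 189 to 354 at CT1, 946 to 2055 at CT10, 1563 to 3144 for time in WT, 0 to 29 for time in KO, 142 to 429 for the interaction, and 0 to 4 in WT and 0 to 3 in KO for CT1 against the other times. For time in KO, 2 genes were called without WT replicate 3 of CT1, WT replicate 1 of CT10, KO replicate 2 of CT19 or KO replicate 4 of CT1. For CT1 against the other times in WT, 4 were called without WT replicate 6 of CT22, and 1 without WT replicate 4 or KO replicate 5 of CT1, and in KO 3 without KO replicate 1 and 1 without KO replicate 5 of CT1. Sign changes were seen for Drd2 over the mean (−0.0029) and Axl at CT10 (−0.027) with the inner retina covariate, and for Cx3cl1 at CT10 (−0.085) with both covariates; none of these was called there by edgeR. The 330 gene results include every core clock gene in every contrast, many of them not called. A result was taken as unchanged if it was called in both fits with the same sign, or called in neither. By this count 322 were unchanged with DESeq2, 317 with voom, 298 with the inner retina covariate and 285 with both covariates (43 no longer called, 1 reversed). The fit without CT10 covered only a part of the 330 results, of which 156 were unchanged and 46 were no longer called.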

Other observations

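The tests of lens genes were chosen before their values were seen.

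Some genes of protein synthesis and folding were lower in KO. Of 76 cytosolic ribosomal protein genes 4 fell over the mean of the times (1 adjusted over the list alone), with a list median of −0.22, camera adjusted p = 8.09e-07, and adjusted p = 0.643 with an estimated correlation. Of 18 heat shock genes 3 fell (3 adjusted over the list alone): Hsp90aa1 (−0.28, SE 0.06), Hspa1a (−0.25, SE 0.07) and Hspa1b (−0.23, SE 0.07), with camera adjusted p = 0.0263, and adjusted p = 0.518 with an estimated correlation. Vascular markers included 5 of 10 that rose (9 adjusted over the list alone, camera adjusted p = 0.00763, and adjusted p = 0.518 with an estimated correlation), with the tight junction gene Cldn5 at 0.80 (SE 0.22) and the pericyte gene Rgs5 at 0.80 (SE 0.19). At CT10, Osmr, a cytokine receptor of the injury list, was higher in KO by 1.37 (SE 0.33) and Lcn2 lower (−0.78, SE 0.23), and Rims1 of the synapse list was higher by 0.81 (SE 0.18).

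Lens genes varied between libraries of the same group. In WT at CT19 the mean of 11 crystallins ran from 1.93 to 6.53 log2 CPM. Over all 32 libraries, which includes differences between groups, this mean ranged from 1.93 to 10.06 log2 CPM. Cryaa, a major lens crystallin, ranged over all libraries from 30.1 to 3654 CPM. The 9 other lens genes, among them Mip, Bfsp2 and Gja3, followed the crystallins within groups with a median Pearson r of 0.955 and a median Spearman rho of 0.955 (median r 0.954 without the 2 farthest libraries; permutation p = 1e-04, the smallest possible, for Mip, with Benjamini-Hochberg adjusted p = 1.3e-04). A median r of this size (0.955) is consistent with RNA from lens tissue in the captured material and argues against crystallin RNA made in photoreceptors with no other lens RNA. No other biological explanation was tested.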
